A study of Mus musculus with 4 samples.

How the data were processed

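RNA was measured in 4 liver samples of mice after hepatectomy, 2 of a control group that received fibrin gel and 2 of a group that received ADSC (adipose-derived stem cells) embedded in fibrin gel, called gelADSC here. Per the labels' protocols, total RNA was extracted with the RNeasy Mini kit and libraries were made with a TruSeq stranded kit for polyadenylated RNA. The time after hepatectomy, the origin of the ADSC and the identity of the animals are not given in the sources used here. Nothing states that the 2 samples of a group came from separate animals. The p-values of single genes therefore rest on a spread between samples that may be technical, moderated across all genes.

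The deposited table holds 1 value per gene and library, named by mouse gene symbol, for 24421 symbols. Its header names no unit. The deposited values were taken as FPKM (fragments scaled by gene length and by the mapped fragments of the library), because Cufflinks 2.2.1 stands among the tools in the submitters' processing notes and because the values behave as such a unit does. They are not whole numbers, each library sums to between 495761 and 517719, and the smallest step between values depends on the gene. Trimmomatic 0.38 and TopHat2 2.1.1 are also named there, per the submitters' processing notes, without an order or settings. The same notes name the human build hg19, which cannot be the reference for a table of mouse symbols, and no annotation version or counting step is given. For that reason no gene coordinates are printed. The 4 columns name the group and a number, 1 and 3 for control and 2 and 3 for gelADSC, while the sample titles number both groups 1 and 2. Libraries are therefore called by the column's number, and no number was used to pair libraries.

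Depth was read from the low values. Within a gene, values under 0.2 FPKM were whole multiples, up to 10, of a step whose ratio between libraries was shared by genes, within a tolerance of 0.001 for 98.6% of 2163 genes examined. Relative to control library 1, the depth was 0.909 in control library 3, 1.22 in gelADSC library 2 and 1.01 in gelADSC library 3. With exon lengths of single-transcript genes in GENCODE M21, the steps put the totals at roughly 19900000 reads in control library 1, 18100000 in control library 3, 24400000 in gelADSC library 2 and 20100000 in gelADSC library 3. These totals are approximate, since 508 of 1177 such genes fell in the most frequent bin of 1% width. At this depth a single read in a 2 kb gene was worth between 0.0205 and 0.0276 FPKM.

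Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 11070 in all. Values were used as deposited, with no further scaling, as log2(FPKM + 1). Each fold change is a difference of mean log2(FPKM + 1), gelADSC minus control, and understates the change of low genes. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Count-based tests were not used, because the values are not counts. Genes at least 2-fold apart whose groups did not overlap were counted as a description without a test. The table was assumed to hold FPKM when the design was fixed, and the test is the one written then.

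A total of 46 lists of pathway genes and cell type markers were fixed before the data were examined, and 40 had at least 5 tested members. Of 976 distinct list symbols, 12 were missing from the table, and 3 of these were found under a synonym in the RefSeq gene table (Peci as Eci2, Utp4 as Cirh1a, Epb42 as Epb4.2), which left 9 unmatched. Lists were tested with camera in limma with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 40 lists. With that preset the test compares members with the other genes and takes genes as nearly independent. Its p-values do not measure the spread between libraries. Camera with an estimated correlation and fry, a test of whether a list moves on balance in 1 direction, were run beside it. With an estimated correlation 0 lists passed the threshold, and the lowest adjusted p was 0.375. Among called lists, the estimate lay below the preset for central vein markers (-0.046), drug metabolism (0.0028), bile acid genes (-0.0028) and sex-biased genes (0.0030). Correlation between genes therefore does not account for the loss of those calls. The estimate was far higher for mitosis (0.98), ribosomal proteins (0.94), cholesterol synthesis (0.91) and S phase (0.86). By fry 0 lists passed in a direction (lowest adjusted p = 0.0506), and 28 passed when members were allowed to change either way. Numbers of called members are given over all genes tested and adjusted over the list alone. List medians relative to the median of all tested genes, and an enrichment of symbol stems (Fisher's exact test, 168 stems of at least 8 tested genes, 336 tests), were added after seeing the data.

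Genes named in the text follow a rule fixed before the data were examined. It takes the 12 higher and 12 lower genes with the largest log2 fold change among those past the threshold, without overlap between groups and with a mean of at least 5 FPKM in the higher group. It adds up to 4 members with the lowest p of each list that is described, and Alb, Mki67, Ccnd1, Pcna, Hgf, Vegfa, Il6, Cyp7a1, Saa1 and Cdkn1a in every case. Unnamed gene models (87 at that level) were left out of the first part. Some genes that the rule takes are not reported here. Other genes named were chosen after their values were seen and are marked so. Genes of families with near-identical copies, among them Cyp2c, Ces1, Mup, Saa, Sult2a, Gml, Gsta and the ribosomal proteins, are uncertain where reads could be split between copies.

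The method was tested on simulated data made from the 11070 tested genes with 2 libraries per group. Of 100 genes changed 2-fold, 54% were called, and of 100 changed 4-fold, 96%. Among the genes left unchanged in the same simulation there were 10 false calls. Noise was drawn from the fitted variances, and few genes were changed. In the data 2702 genes were called and many moved together, so these rates need not hold there. A list of 30 genes raised by 0.7 on the log2 scale was called with the preset correlation but not with an estimated one (adjusted p = 0.195), and 0 of 40 unchanged lists were called with either. Genes were simulated as independent of each other, so the raised list lost its call without any correlation. For the same reason the simulation does not show how often unchanged lists are called when their genes move together. In the data the estimated correlation was 0.98 for mitosis and 0.94 for ribosomal proteins. Alternatives tried were pseudocounts of 0.1 and 5, no filter on low values, a minimum mean of 10 FPKM, median ratio scaling, quantile normalization, limma without a trend, and each library left out in turn. Figures were drawn with matplotlib 3.10.9.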

Results

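Liver RNA was compared between mice that received fibrin gel alone after hepatectomy (control, 2 libraries) and mice that received adipose-derived stem cells embedded in fibrin gel (gelADSC, 2 libraries). The comparison asks how the liver transcriptome differed when the gel carried ADSC. Values are FPKM, given as mean ± SD with n = 2 libraries per group throughout, and log2 changes are gelADSC minus control. The libraries held roughly 18100000 to 24400000 reads, as inferred from the smallest steps of the values. Between the control libraries the Pearson correlation across genes was 0.98, between the gelADSC libraries 0.97, and between groups 0.88 to 0.92. Genes are not independent replicates, and these correlations describe the libraries. The first principal component held 81.2% of the variance and separated the groups.

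Livers of the gelADSC group had more transcript of hepatocyte metabolic enzymes and of S phase and mitosis genes, and less of ribosomal protein, cholesterol synthesis and immediate early genes. These lists were called by camera with a preset correlation, and 0 lists were called with an estimated correlation or by fry. The higher values of mitosis genes lay mostly in gelADSC library 3, with a median log2 difference from the controls of 3.16 against 0.62 in library 2. Car3, a cytosolic carbonic anhydrase, rose from 5.82 ± 3.18 to 667 ± 18.1 FPKM (n = 2 each, log2 change 6.70, SE 0.30, limma adjusted p = 1.14e-05). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, read 0 and 0.0132 FPKM in the control libraries and 56.9 and 15.0 FPKM in the gelADSC libraries (adjusted p = 0.000527). Cidec, a lipid droplet protein, fell from 195 ± 30.7 to 3.14 ± 0.332 FPKM (n = 2 each, log2 change -5.56, SE 0.20, limma adjusted p = 8.23e-06). Sprr1a, a small proline-rich protein of the cell envelope, read 181 and 58.1 FPKM in the controls and 0.208 and 0 FPKM in gelADSC (adjusted p = 9.26e-05).

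Of 11070 genes tested, 766 were higher and 1936 lower in gelADSC at a limma adjusted p under 0.05, so that 28.3% of the calls were higher. The median log2 change of all tested genes was -0.25. Median ratio scaling, which removes that shift, gave 952 higher and 948 lower genes (50.1% higher), and quantile normalization gave 931 and 1000 (48.2% higher). List medians are therefore also given relative to the median of all tested genes. Groups did not overlap for 2130 higher and 5595 lower genes, 69.8% of those tested, where chance gives 33.3% for a gene taken alone. All genes share the same libraries, so a common shift can separate many at once. The share is a description and not a test of a group effect. Without overlap and at least 2-fold apart were 596 higher and 935 lower genes. Control library 1 weighed most on the count. Without it 303 genes were higher and 331 lower. Without control library 3, 552 were higher and 1708 lower, without gelADSC library 2, 775 and 1209, and without gelADSC library 3, 657 and 1580. In these fits the spread comes from the group with 2 libraries, and the lone library is assumed to vary like it.

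The 12 genes with the largest increases were Car3, Cyp2c54, Serpina6, Inmt, Ces1d, Cyp8b1, Sult2a8, Cyp2c50, Cyp7a1, Keg1, Cyp2c29 and Ces1f, with log2 changes from 6.70 down to 4.58. Serpina6, which encodes corticosteroid-binding globulin, rose from 0.762 ± 0.330 to 112 ± 24.3 FPKM (n = 2 each). Inmt, a methyltransferase, rose from 3.26 ± 1.71 to 245 ± 29.5 FPKM (n = 2 each). Cyp8b1, which directs bile acid synthesis towards cholic acid, rose from 0.404 ± 0.0108 to 79.9 ± 74.7 FPKM (n = 2 each), with 133 FPKM in gelADSC library 2 and 27.1 FPKM in library 3. The Cyp2c, Ces1 and Sult2a genes belong to families with near-identical copies, so the share of each copy is uncertain. The 12 largest decreases were those of Sprr1a, Cidec, Sult1e1, Slc51b, Gml2, Ier3, Mup15, Gsta1, Tnfrsf12a, Fgf21, Cgref1 and Gml. Sult1e1, an estrogen sulfotransferase, fell from 208 ± 25.2 to 4.71 ± 4.43 FPKM (n = 2 each). Tnfrsf12a, the receptor of the cytokine TWEAK, fell from 294 ± 104 to 15.9 ± 4.57 FPKM (n = 2 each). Fgf21, a metabolic hormone made by the liver, fell from 60.4 ± 41.02 to 2.45 ± 0.574 FPKM (n = 2 each). Gml2 (25.9 and 15.1 FPKM in the controls) and Gml (16.9 and 11.5 FPKM) were listed at 0 in both gelADSC libraries, so no fold is given. Mup15, Gsta1, Gml and Gml2 also have near-identical copies. All 24 of these genes were called under each alternative setting in which they were tested, including those that left 1 library in a group and took the spread from the other group.

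**Figure D1:**
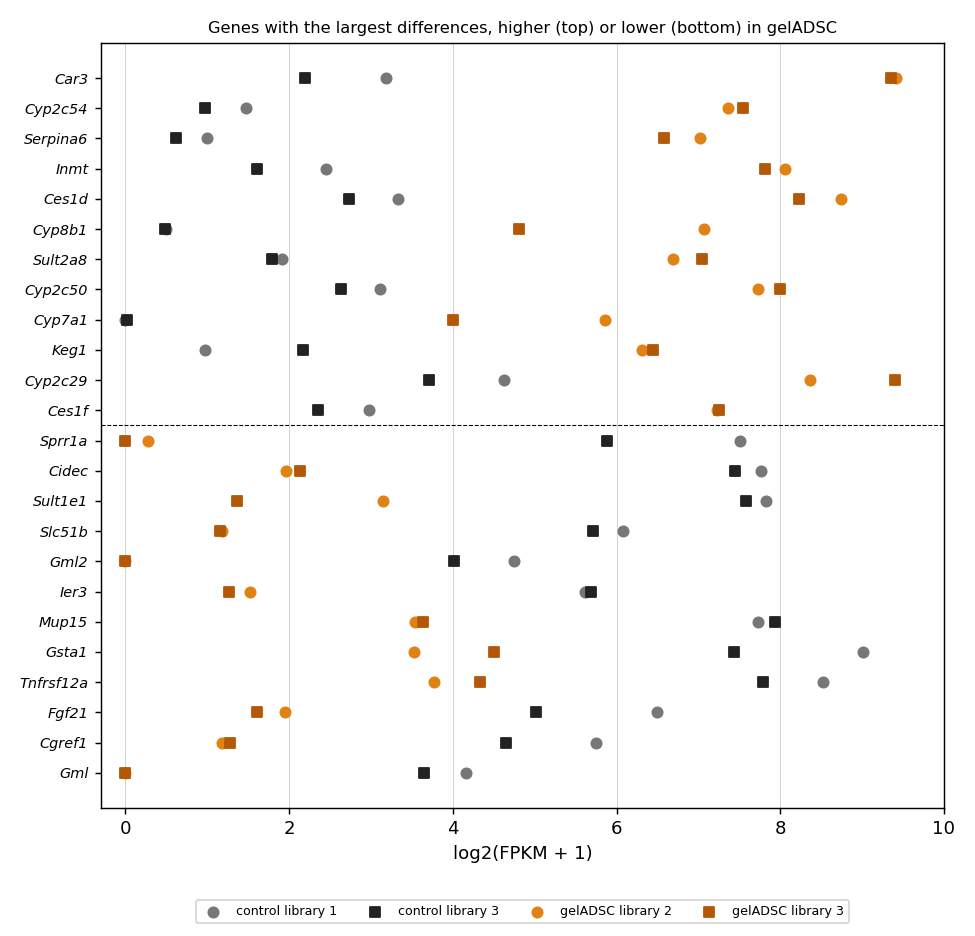
Each point is the value of a library as log2(FPKM + 1) for the 12 genes with the largest increases and the 12 with the largest decreases in gelADSC, gray and black for control libraries 1 and 3 and light and dark orange for gelADSC libraries 2 and 3. The groups do not overlap for any of these genes, and Gml and Gml2 lie at 0 in both gelADSC libraries.

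Markers of hepatocytes near the central vein rose as a group. Of 16 tested markers 13 rose and 1 fell, or 14 and 1 adjusted over the list alone, with a median log2 change of 1.94 (2.19 relative to all genes, camera adjusted p = 4.81e-14). The adjusted p was 0.375 with an estimated correlation, which was -0.046 for this list. Rgn, which encodes regucalcin, rose from 37.6 ± 6.73 to 613 ± 53.4 FPKM (n = 2 each), and Glul, glutamine synthetase, from 36.2 ± 5.01 to 211 ± 21.5 FPKM (n = 2 each). Slc1a2, a glutamate transporter, and Cyp1a2 rose with log2 changes of 2.62 and 3.12. The member that fell was Lect2, with a log2 change of -1.01, named after its value was seen. No member was called lower with median ratio scaling, quantile normalization, no filter or without control library 3. Among cytochromes and conjugating enzymes of drug metabolism, 15 of 25 rose and 4 fell, or 16 and 4 adjusted over the list alone, with a median of 1.56 (1.81 relative to all genes, camera adjusted p = 2.55e-10). With an estimated correlation, 0.0028 for this list, that adjusted p was 0.375. The counts were 14 and 1 with median ratio scaling or quantile normalization, with no filter or without control library 1, 11 and 1, and without control library 3, 13 and 2. Ugt2b1, a glucuronosyltransferase, rose from 9.36 ± 0.298 to 92.6 ± 21.3 FPKM (n = 2 each).

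Markers of hepatocytes near the portal vein went both ways, 5 of 15 higher and 3 lower, or 7 and 3 adjusted over the list alone. Their median was 0.69 (0.94 relative to all genes, camera adjusted p = 0.00519, and adjusted p = 0.849 with an estimated correlation). Cyp2f2 rose from 30.7 ± 7.44 to 389 ± 122 FPKM (n = 2 each) and Hal, histidine ammonia lyase, rose with a log2 change of 1.56. Arg1, the arginase of the urea cycle, fell with a log2 change of -1.33, and Sox9, a transcription factor of bile duct cells, with -2.07. The list was no longer called with median ratio scaling (adjusted p = 0.110), quantile normalization (0.117) or without control library 1 (0.110). Of the list 3 rose and 1 fell with median ratio scaling, with quantile normalization 3 and 2, and with no filter or without control library 1, 1 and 2. The call of Arg1 was lost with median ratio scaling (0.0579), and that of Hal there (0.0502) and without control library 1 (0.0501).

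Genes of bile acid synthesis and transport were split, with 12 of 22 higher and 6 lower, the same counts adjusted over the list alone. Their median was 1.01 (1.26 relative to all genes, camera adjusted p = 0.00038, and adjusted p = 0.623 with an estimated correlation). The enzymes Cyp7a1 and Cyp7b1 rose, the latter from 5.11 ± 0.375 to 41.7 ± 17.1 FPKM (n = 2 each), as did Slc10a1, the sodium-dependent bile acid uptake transporter, from 27.3 ± 1.73 to 170 ± 34.7 FPKM (n = 2 each). Slc51b, a subunit of the basolateral bile acid exporter, fell from 59.2 ± 10.8 to 1.24 ± 0.0277 FPKM (n = 2 each). With median ratio scaling the list's adjusted p was 0.0833. Of the list 8 rose and 3 fell without control library 1. Among 26 genes of the urea cycle and amino acid catabolism 11 rose and 3 fell, or 15 and 4 adjusted over the list alone, with a median of 0.83 (1.08 relative to all genes, camera adjusted p = 3.1e-07, and adjusted p = 0.849 with an estimated correlation). Otc, Hgd and Hpd rose with log2 changes of 2.14, 1.91 and 3.25, while Sdsl fell with -1.61. The control libraries also differed in this list, with 24 of the 26 genes higher in control library 3 than in library 1 and a median difference of 0.52. Here 6 rose and 3 fell without control library 1, with median ratio scaling 8 and 1, and with no filter 6 and 2.

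Of 30 secreted hepatocyte proteins 13 rose and 2 fell, or 17 and 2 adjusted over the list alone, with a median of 0.68 (0.93 relative to all genes, camera adjusted p = 2.26e-09, and adjusted p = 0.849 with an estimated correlation). Hrg, histidine-rich glycoprotein, rose from 151 ± 51.0 to 872 ± 157 FPKM (n = 2 each), and the coagulation factors F10, F7 and F5 rose with log2 changes of 1.87, 1.80 and 1.61. The counts were 5 and 2 without control library 1, without control library 3, 11 and 1, with median ratio scaling 13 and 0, with quantile normalization 11 and 1, and with no filter 8 and 1. Alb, serum albumin, read 30018 ± 2672 FPKM in control and 30176 ± 11531 FPKM in gelADSC (n = 2 each, log2 change -0.04, SE 0.37, limma adjusted p = 0.942). Acute phase proteins were called higher as a list, but 7 of 29 rose and 6 fell, or 8 and 7 adjusted over the list alone, with a median of 0.21 (0.46 relative to all genes, camera adjusted p = 0.0177, and adjusted p = 0.849 with an estimated correlation). Saa4 rose from 60.8 ± 22.0 to 252 ± 55.7 FPKM (n = 2 each), while the metallothioneins Mt1 and Mt2 and the serpin Serpina3m fell with log2 changes of -1.45, -1.60 and -1.39. Between the control libraries the list differed by a median of 0.27, more than between the groups, and between the gelADSC libraries by -0.45 (library 3 minus the other in each). The adjusted p of this list ranged from 3.1e-08 to 0.632 over the alternatives, and the call was lost in 5 of 11, among them without control library 1 (0.273) and without gelADSC library 2 (0.632). Of the list 1 rose and 1 fell without control library 1 or with no filter, without control library 3, 7 and 3, and without gelADSC library 3, 12 and 5. The counts were 5 and 3 with median ratio scaling, and with quantile normalization 6 and 3. The calls of Mt1 and Mt2 were lost without control library 1 (0.0617 and 0.0572). Saa1 read 4734 and 6813 FPKM in the controls and 16936 and 4077 FPKM in gelADSC libraries 2 and 3, and was called higher without library 3 (adjusted p = 0.000274).

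Genes of DNA replication and mitosis were higher in gelADSC. Of 30 S phase genes 16 rose and 0 fell, or 21 and 0 adjusted over the list alone, with a median of 0.94 (1.19 relative to all genes, camera adjusted p = 4.81e-14, and adjusted p = 0.849 with an estimated correlation). Tk1, thymidine kinase, rose from 1.44 ± 0.532 to 23.8 ± 4.89 FPKM (n = 2 each), and Uhrf1, Mcm5 and Mcm6 rose with log2 changes of 1.72, 1.75 and 1.35. Pcna, the sliding clamp of DNA polymerase, read 21.02 ± 2.09 and 30.3 ± 11.9 FPKM (n = 2 each, limma adjusted p = 0.239). Of 29 mitosis genes 8 rose and 0 fell, or 27 and 0 adjusted over the list alone, with a median of 1.98 (2.22 relative to all genes, camera adjusted p = 3.25e-12, and adjusted p = 0.849 with an estimated correlation). Mki67, a marker of cycling cells, read 0.0946 and 0.143 FPKM in the controls and 1.55 and 12.5 FPKM in gelADSC libraries 2 and 3 (log2 change 2.39, SE 0.63, limma adjusted p = 0.0277). Top2a, Cdk1 and Aurkb rose with log2 changes of 2.66, 2.51 and 2.05. Leaving out control library 1 gave adjusted p values of 0.224 for Mki67, 0.177 for Top2a, 0.242 for Cdk1, 0.262 for Aurkb, 0.0848 for Mcm5 and 0.126 for Mcm6. Without control library 3 they were 0.144 for Mki67, 0.103 for Top2a, 0.149 for Cdk1 and Aurkb and 0.0931 for Mcm6, and without gelADSC library 3 the value was 0.0582 for Mcm6.

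The gelADSC libraries differed from each other in these genes. All 29 mitosis genes and all 30 S phase genes read higher in gelADSC library 3 than in library 2, by medians of 2.41 and 0.82 on the log2 scale. Against the mean of the controls, the mitosis median was 0.62 in library 2 and 3.16 in library 3. The number of mitosis genes called was 0 without control library 1, 0 without control library 3, 29 without gelADSC library 2 and 2 without gelADSC library 3, and it was 0 with median ratio scaling, with quantile normalization and with no filter. It also turned on the pseudocount, with 20 called at 0.1 and 0 at 5, where the adjusted p was 0.0779 for Mki67, 0.0523 for Top2a, 0.0764 for Cdk1 and 0.0822 for Aurkb. For S phase genes the number was 2, 3, 24 and 4 with the same libraries left out, and 4 with no filter. With a gelADSC library left out the spread comes from the control libraries alone, in which these genes were low, and with a control left out, from the gelADSC libraries alone. The list tests for both passed, with the preset correlation, under all alternatives in which they were run. The preset of 0.01 takes members as nearly independent, while the estimated correlation was 0.98 for mitosis and 0.86 for S phase. Passing with the preset therefore does not show that these changes are stable between libraries.

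**Figure D2:**
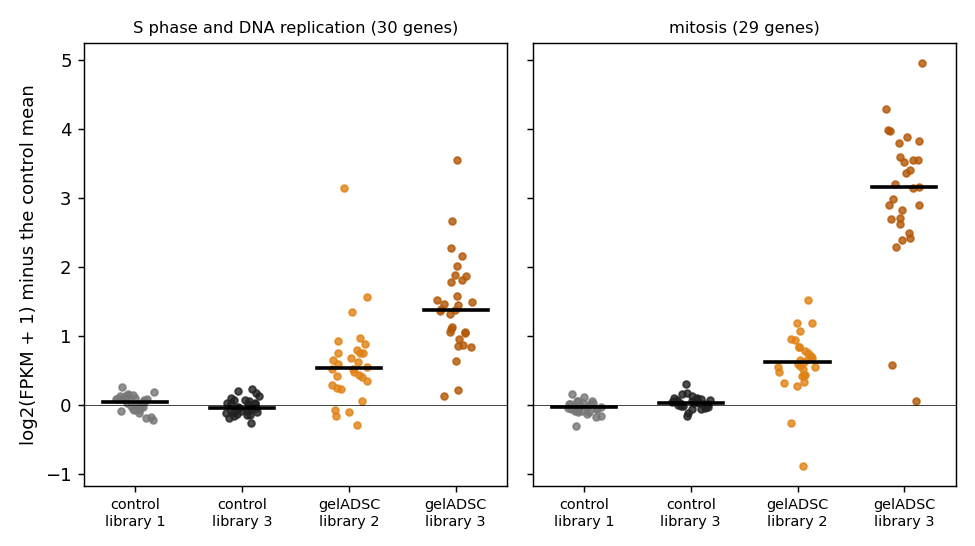
Each point is a gene, as log2(FPKM + 1) minus the mean of the control libraries, for the 30 S phase and 29 mitosis genes in each library, with a bar at the median. The mitosis genes have a median of 0.62 in gelADSC library 2 and 3.16 in gelADSC library 3.

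Genes of G1 entry and the immediate early response were lower, with 14 of 23 called and 0 higher, or 16 and 0 adjusted over the list alone. Their median was -1.03 (-0.78 relative to all genes, camera adjusted p = 0.00048, and adjusted p = 0.849 with an estimated correlation). Ier3 fell from 49.3 ± 1.87 to 1.65 ± 0.331 FPKM (n = 2 each), and Klf6, Btg2 and Socs3 fell with log2 changes of -2.02, -1.56 and -1.49. With median ratio scaling 5 of the list were lower and 1 higher, with quantile normalization 5 were lower, with no filter 6 and without control library 1, 3. The call of Socs3 was lost with either scaling (0.0633) and without control library 1 (0.0599). Ccnd1, cyclin D1, fell from 75.8 ± 12.5 to 43.9 ± 2.80 FPKM (n = 2 each, adjusted p = 0.0266), but its adjusted p was 0.187 with median ratio scaling and 0.136 with quantile normalization. It was 0.0662 without control library 1, 0.0849 without control library 3 and 0.108 without gelADSC library 2. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, fell, from 133 and 101 FPKM in the controls to 5.56 and 40.5 FPKM in gelADSC libraries 2 and 3 (adjusted p = 0.0205). That call was lost with median ratio scaling (0.104), quantile normalization (0.101), no filter (0.117), without control library 1 (0.217) and without control library 3 (0.112).

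Ribosomal protein genes were lower, 25 of 28 called and 0 higher, or 26 and 0 adjusted over the list alone, with a median of -0.97 (-0.72 relative to all genes, camera adjusted p = 2.47e-07, and adjusted p = 0.849 with an estimated correlation). Rpl13 fell from 45.9 ± 8.70 to 16.5 ± 1.69 FPKM (n = 2 each), and Rps4x and Rpl27 fell with log2 changes of -1.34 and -1.19. The number called was 14 with median ratio scaling, 16 with quantile normalization, 11 with no filter, 2 without control library 1 and 15 without gelADSC library 2. The adjusted p was 0.0603 for Rpl27 and 0.0535 for Rps4x without control library 1. All 28 read lower in control library 3 than in control library 1, by a median of 0.37 on the log2 scale. Of 25 ribosome biogenesis genes 10 fell and 0 rose, or 17 and 0 adjusted over the list alone, with a median of -0.67 (-0.42 relative to all genes, camera adjusted p = 0.00263, and adjusted p = 0.849 with an estimated correlation). Ltv1, Bop1, Nop58 and Nop2 were among those that fell, the last 3 with log2 changes of -0.80, -0.99 and -0.86. Without gelADSC library 3 the list's adjusted p was 0.0533, and without control library 1, 0 of its genes were called. Called were 2 with median ratio scaling or quantile normalization, with no filter 0, without gelADSC library 2, 3, and without gelADSC library 3, 4. Without gelADSC library 2 the adjusted p was 0.121 for Bop1, 0.0705 for Nop58 and 0.0551 for Nop2, and without gelADSC library 3 it was 0.0648 for Nop2. The calls of Nop58 and Nop2 were also lost with median ratio scaling (0.0703 and 0.0720) and quantile normalization (0.0947 and 0.0823). Of the 25 genes 1 was higher in control library 3 than in control library 1, with a median difference of -0.48.

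Genes of cholesterol synthesis and other targets of SREBP2, the transcription factor of sterol supply, were lower, 17 of 25 called and 1 higher, or 20 and 1 adjusted over the list alone. Their median was -1.27 (-1.02 relative to all genes, camera adjusted p = 0.000333, and adjusted p = 0.849 with an estimated correlation). Mvd fell from 73.3 ± 4.66 to 11.8 ± 6.78 FPKM (n = 2 each), and Hsd17b7 fell with a log2 change of -2.26. All 25 genes read lower in gelADSC library 3 than in library 2, by a median of 0.94. Of the 25, 24 read higher in control library 3 than in control library 1, with a median difference of 0.44. With median ratio scaling 2 were called lower, with quantile normalization 4 and with no filter 4. Without control library 1, 2 were called lower, and without control library 3, 4, when the list's adjusted p was 0.187. The adjusted p of Mvd was 0.0503 without control library 1.

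Markers of stellate cells and fibroblasts were called higher, with 7 of 20 higher and 1 lower, the same adjusted over the list alone. Their median was 0.33 (0.58 relative to all genes, camera adjusted p = 0.00088, and adjusted p = 0.849 with an estimated correlation). The control libraries differed by more, with 1 of the 20 genes higher in control library 3 than in library 1 and a median difference of -0.89. Cxcl12, a chemokine, rose from 21.7 ± 0.625 to 63.3 ± 18.4 FPKM (n = 2 each), and Colec11, Lum and Colec10 rose with log2 changes of 1.56, 1.54 and 1.36. The call was lost without control library 3 (adjusted p = 0.146), without gelADSC library 2 (0.113) and with a minimum mean of 10 FPKM (0.425). In the fit without control library 1 or with no filter 2 members were higher and 0 lower, without control library 3, 3 and 4, and without gelADSC library 2, 5 and 3. Leaving out control library 1 gave adjusted p values of 0.0662 for Cxcl12 and 0.0712 for Colec10, and without control library 3 it was 0.0637 for Colec10. Of 15 sex-biased liver genes 6 rose and 1 fell, or 6 and 2 adjusted over the list alone, with a median of 0.29 (0.54 relative to all genes, camera adjusted p = 0.00088, and adjusted p = 0.623 with an estimated correlation). Cyp7b1 and Hsd3b5, higher in males, and Cyp2a4, higher in females, rose. With quantile normalization the list's adjusted p was 0.0529. Without either control library, or with no filter, 3 rose and 1 fell, without gelADSC library 2, 6 and 3, and without gelADSC library 3, 7 and 2.

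Of the 25 tested lists that were not called, several had members that passed singly. Among inflammatory cytokines and NF-kB targets 9 of 16 fell and 1 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.217). The chemokine Ccl2 fell from 31.3 ± 4.29 to 2.23 ± 2.1 FPKM (n = 2 each), and Cxcl2 and Ccl7 fell with log2 changes of -1.90 and -2.29, while Ccl5 rose with 1.84. Without gelADSC library 2 this list was called lower (adjusted p = 1.16e-07), as it was with no filter (0.0384). But only 2 of its genes were lower with median ratio scaling or no filter, 3 with quantile normalization, 1 without control library 1 and 5 without control library 3, with 0 higher in each. Without gelADSC library 3, 3 were higher and 4 lower. Leaving out control library 1 gave adjusted p values of 0.0505 for Ccl2, 0.121 for Ccl7 and 0.165 for Ccl5, and without control library 3 it was 0.0878 for Ccl5. With median ratio scaling the calls of Ccl5 (0.0661) and Ccl7 (0.0554) were lost, and with quantile normalization that of Ccl5 (0.0755). Among growth factors and receptors of the liver 5 of 24 rose and 7 fell, or 6 and 9 adjusted over the list alone (camera adjusted p = 0.501). The counts were 2 and 2 without control library 1, with no filter 2 and 4, without gelADSC library 2, 3 and 6, and without gelADSC library 3, 3 and 7. Egfr rose from 22.1 ± 2.77 to 112 ± 11.1 FPKM (n = 2 each), and Igfbp1 fell from 1044 ± 489 to 110 ± 10.8 FPKM (n = 2 each). Hgf, the hepatocyte growth factor, read 4.13 ± 0.967 and 3.53 ± 0.668 FPKM (n = 2 each, limma adjusted p = 0.608). Vegfa, the vascular growth factor, read 40.5 ± 2.98 and 33.9 ± 5.59 FPKM (n = 2 each, limma adjusted p = 0.366). Il6 lay below the level tested, at 0.231 and 0.0508 FPKM in the controls and 0.0377 and 0 FPKM in gelADSC. Other lists that were not called passed with 1 library left out. The interferon response was called higher without control library 3 (adjusted p = 0.000398) and without gelADSC library 3 (0.00203), and with a minimum mean of 10 FPKM (0.0137). NRF2 targets were called lower without gelADSC library 2 (0.000678) and without gelADSC library 3 (0.000268). TGF-beta and matrix genes were called lower without gelADSC library 2 (0.0401), p53 targets without gelADSC library 3 (0.00651) and the unfolded protein response with no filter (0.0458).

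**Figure D3:**
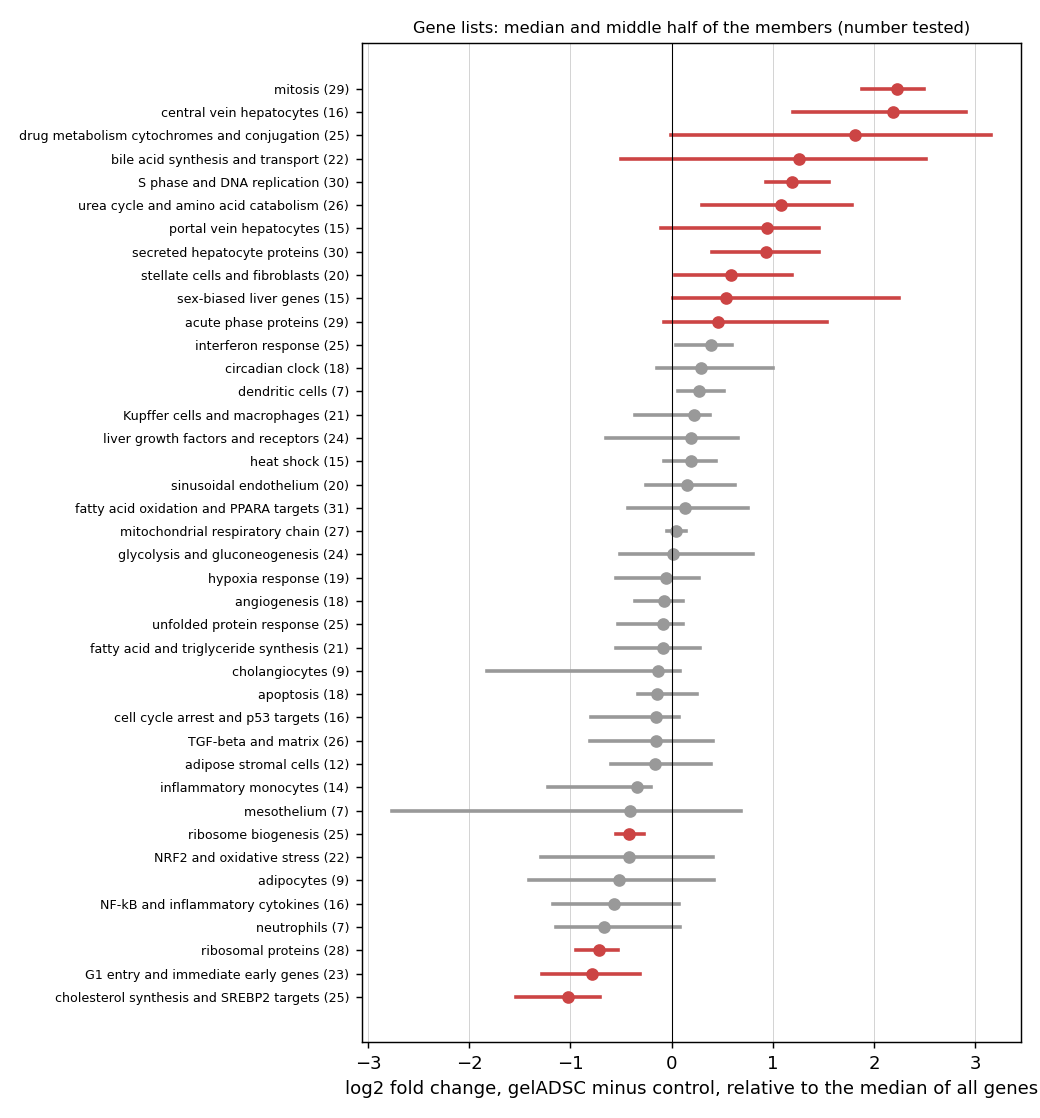
Points are medians and lines the middle 50% of the log2 changes of the members of each list, relative to the median of all tested genes, with the number tested in brackets. Lists called by camera with the preset correlation are red, 11 higher and 4 lower, and the others are gray.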

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

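With the preset correlation, 8 of the 15 called lists were called in every alternative (S phase, mitosis, G1 entry, secreted proteins, urea cycle, drug metabolism, ribosomal proteins, central vein), although mitosis had too few members for a test with a minimum mean of 10 FPKM, and 0 called lists turned direction. Of 153 called named genes 85 were called in each alternative in which they were tested, and 68 lost the call in at least 1. No called gene was called in the opposite direction in any alternative. The preset correlation takes list members as nearly independent, so a list call kept in every alternative does not show stability between libraries. No paired analysis was possible because the groups share only the column number 3. Depth, at most 24400000 reads, limits genes near the lowest level tested. The cause was not tested for any change below, except where fewer libraries or genes entered.

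Where a library was left out, the lone library of its group was assumed to vary like the other group. Leaving out each library in turn gave 303 to 775 higher and 331 to 1708 lower genes, 646 to 1450 genes lower by 2-fold without overlap, and 3 to 11 lists called lower. With a pseudocount of 5, 342 and 462 genes were 2-fold higher and lower without overlap. With no filter 730 genes were called lower. With a minimum mean of 10 FPKM, where 4812 genes were tested, 509 were called higher, and 335 and 577 were 2-fold higher and lower without overlap. Median ratio scaling gave 948 lower genes (554 by 2-fold without overlap) and quantile normalization 1000 (613). Lists called up and down were 0 and 0 with an estimated correlation and 0 and 0 by fry.

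Lists that were not called changed camera or fry direction in some settings; their medians there follow. With no filter these were -0.11 (liver growth factors), -0.21 (glycolysis), 0.19 (mesothelium) and -0.00028 (adipose stromal cells). With a minimum mean of 10 FPKM they were -0.38 (fatty acid synthesis) and -0.20 (respiratory chain). Median ratio scaling gave 0.086 for the respiratory chain and quantile normalization -0.16 for glycolysis. By fry they were -0.052 (liver growth factors), -0.24 (glycolysis), -0.11 (fatty acid oxidation), -0.061 (heat shock) and -0.023 (Kupffer cells).

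With each library left out, medians ranged from -0.22 to 0.089 for liver growth factors, -1.27 to -0.58 for NF-kB, -0.22 to 0.29 for the interferon response, -0.29 to -0.23 for glycolysis, -0.13 to 0.0061 for fatty acid oxidation and -0.37 to -0.20 for fatty acid synthesis. They ranged from -0.72 to -0.21 for TGF-beta and matrix, -0.26 to -0.12 for the respiratory chain, -0.15 to 0.43 for the clock, -0.16 to 0.069 for endothelium, -0.78 to -0.052 for adipose stromal cells, -1.61 to -0.20 for adipocytes, -0.17 to 0.14 for Kupffer cells and -1.52 to -0.27 for neutrophils.

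Named genes that were not called also changed sign or reached 0. Median ratio scaling gave 0.0024 for H2-Ab1, 0.25 for Alb, 0.057 for Hgf and 0.029 for Vegfa, and quantile normalization 0.015 for H2-Ab1, 0.044 for Vegfa and 0 for Alb, which this method forces on the gene ranked first in all 4 libraries. With each library left out, Alb ranged from -0.44 to 0.36, Hgf from -0.37 to 0.018 and Saa1 from -0.48 to 1.58.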

Other observations

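Symbol stems, tested for enrichment after the data were seen, gave further families. Of 63 tested Cyp genes 35 were higher and 4 lower (Fisher's exact test, adjusted p = 2.28e-22), and of 14 Ugt genes 11 were higher. Ces (8 of 12), Hsd (8 of 13) and Aldh (8 of 15) genes were also higher more often than chance gives. Lower were 37 of 45 Rpl and 30 of 40 Rps genes (adjusted p = 8.06e-19 and 3.07e-13), the latter stem including kinase genes such as Rps6ka4, 9 of 14 Mup genes, which encode major urinary proteins with near-identical copies, 20 of 51 Eif genes of translation initiation and 8 of 15 Dusp phosphatase genes. With median ratio scaling or quantile normalization 1 Mup gene and 1 Dusp gene were higher and 6 of each were lower, and 9 or 4 Eif, 21 or 23 Rpl and 16 or 19 Rps genes were lower. With quantile normalization 4 of 51 Eif genes is no more than the share of all genes, 1000 of 11070, so that family depends on the scaling.

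With all 4 libraries and the settings chosen first, lists of cell types other than hepatocytes and stellate cells were not called, although single markers changed. Some passed with 1 library left out. Cholangiocytes were called lower without gelADSC library 2 (adjusted p = 0.0118) and without gelADSC library 3 (0.0255), mesothelium likewise (0.00579 and 0.000814), and dendritic cells higher with no filter (0.0254). The lists of T and NK cells, B and plasma cells, erythroid cells, platelets, pancreatic acinar cells and skeletal muscle had fewer than 5 tested members. Among markers of inflammatory monocytes 4 of 14 fell (camera adjusted p = 0.133). The list was called lower without control library 1 (adjusted p = 0.0122, 3 lower) and without gelADSC library 2 (3.44e-08, 11 lower), and without gelADSC library 3, 5 were lower and 2 higher. All 14 read lower in gelADSC library 3 than in library 2, by a median of 0.94. The 4 include Cd14, from 53.5 ± 22.7 to 2.89 ± 1.85 FPKM, and Chil3, from 39.1 ± 13.5 to 2.18 ± 2.30 FPKM (n = 2 each). The macrophage marker Cd68 fell from 80.9 ± 26.3 to 14.1 ± 3.49 FPKM (n = 2 each), with 3 of 21 markers of that list lower (adjusted p = 0.585). Lower were 1 without control library 1, 5 without gelADSC library 2, and without gelADSC library 3, 4 with 3 higher. Other markers went up. Prtn3, a protease of neutrophil precursors, rose from 2.33 ± 0.886 to 25.9 ± 18.3 FPKM (n = 2 each, limma adjusted p = 0.00319), with 1 of 7 tested neutrophil markers higher and 2 lower (camera adjusted p = 0.583). None were called without control library 1, and without gelADSC library 2 the list was called lower (0.0403), with 1 higher and 5 lower. The call of Prtn3 was lost without control library 1 (adjusted p = 0.0945) and with no filter. Alas2, an enzyme of heme synthesis in erythroid cells, rose from 10.5 ± 0.681 to 39.5 ± 0.862 FPKM (n = 2 each, limma adjusted p = 0.000531). The keratins Krt8 and Krt18, held in the mesothelium list but also made by hepatocytes, fell with log2 changes of -3.36 and -3.21. The origin of the ADSC is not given, so markers of adipose stromal cells do not tell whether implanted cells were in the samples. Of 12 tested markers of adipose stromal cells, the type that was implanted, 0 rose and 3 fell (camera adjusted p = 0.770), namely Itgb1, Cd44 and Nt5e. None of these was called without control library 1 (adjusted p = 0.0957 for Itgb1, 0.149 for Cd44 and 0.174 for Nt5e), without gelADSC library 2, 5 fell, and with either scaling 1 fell. The adjusted p of Cd44 was also 0.0988 without control library 3 and 0.161 without gelADSC library 3, when 1 marker rose and 2 fell. Pdk4, a kinase that restrains pyruvate oxidation, fell from 55.8 ± 3.16 to 11.5 ± 4.02 FPKM (n = 2 each), with 5 of 24 glycolysis and gluconeogenesis genes higher and 5 lower (adjusted p = 0.622), 1 and 2 without control library 1, and 2 and 4 with median ratio scaling. The lipid droplet protein Plin2 fell from 1747 ± 524 to 299 ± 31.5 FPKM (n = 2 each). The globin genes Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Hbb-b1 and Hbb-b2 were listed at 0 in all 4 libraries and Ass1, an abundant liver enzyme, at no more than 0.151 FPKM, so a 0 in this table can be a failed estimate. The globin genes, Ass1, Alas2 and Saa3 were named after their values were seen. Saa3 read 15.7 and 11.2 FPKM in the controls and 1867 and 14.7 FPKM in gelADSC libraries 2 and 3.

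All tests in the following paragraphs were chosen after the results were seen. The labels name no difference between the groups other than the treatment. The time after hepatectomy and the identity of the animals are not given, so a difference in these cannot be told apart from the treatment.

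Mitosis genes were higher in gelADSC library 3 than in library 2 by a median of 2.41 with a lower quartile of 2.02. A difference in scaling or depth would move all genes, but the median difference of all tested genes was 0.105. More myeloid cells in library 3 would raise their markers, but the upper quartile over 37 macrophage, monocyte and neutrophil markers was -0.29, leaving out Hp, Fn1 and Lcn2, which hepatocytes also make, a choice made after seeing the data. Prtn3, among those 37, went the other way, with 12.97 FPKM in library 2 and 38.8 FPKM in library 3, while Mpo and Elane, other precursor genes, stayed at or under 0.327 FPKM in all 4 libraries, so cycling myeloid precursors stay open. Lymphocytes stay open too, since 1 of the T and NK and 2 of the B and plasma cell markers reached the level tested. Ccl5 read 6.87 and 1.96 FPKM in libraries 2 and 3 and Cd74 17.8 and 15.6 FPKM, while Cd79a (0.525 and 0.898 FPKM) and Cd79b (0.479 and 0.829 FPKM) were higher in library 3. Also open is a candidate explanation that the livers were taken in different phases of regeneration, which the labels cannot test.

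Ribosomal protein genes were lower by a median of 0.97. Gene length is a candidate explanation because short transcripts were lower across genes (Spearman's rho 0.137 between length and log2 change over 10702 genes, which are not independent). Against 10000 random lists matched on length and expression, 0.01% had a median as low, the real list counted, the smallest share they can give. The lowest of their medians was -0.82. The random lists were drawn gene by gene, while the ribosomal protein genes moved together, with an estimated correlation of 0.94. Medians of such a block vary more than those of the random lists, so the share overstates the evidence against length. A shift by library scaling is argued against by the upper quartile of the changes relative to all genes, -0.53. Since 14 and 16 of the 28 genes were called under median ratio scaling and quantile normalization, and control library 1 read higher than control library 3 in all 28, a difference in RNA quality between libraries may still contribute and was not tested.

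Hepatocyte metabolism genes were higher in gelADSC, and a lower share of hepatocytes in the control livers is a candidate explanation, examined under 3 rules in turn. The first test used other cell types, whose markers should all be lower in gelADSC. Stellate cell markers were called higher instead (camera adjusted p = 0.00088) and, with all 4 libraries, no other type was called lower. The adjusted p of this list was 0.849 with an estimated correlation and 0.464 by fry. But 0 lists passed either of these tests in a direction, so those values do not single out stellate markers. The stellate call is weak all the same. It was also lost without control library 3 (0.146), without gelADSC library 2 (0.113) and with a minimum mean of 10 FPKM (0.425). With 1 library left out, monocytes, neutrophils and cholangiocytes were called lower in 1 or 2 of the 4 fits, as the explanation predicts, so this test carries little weight alone. Mesothelium was also called lower in some of these fits. Its list holds Krt8 and Krt18, which hepatocytes also make and which fell with log2 changes of -3.36 and -3.21. A lower share of hepatocytes in the control livers would raise them, so the mesothelium call is not counted as a prediction met. A second test, written after the first was known, used the 10 most abundant secreted hepatocyte transcripts, which a change in share would move by about the same factor as 39 metabolism genes, whose median was 1.56 and lower quartile 0.21. Their median log2 change was 0.30 and their upper quartile 0.66. Of the 10, 7 were above 0, led by Gc at 0.88 (adjusted p = 0.0276, the only one past the threshold), Ttr at 0.69 and Apoc1 at 0.68, and 3 below, Alb at -0.04, Trf at -0.54 and Apoa1 at -0.70. Against the lower quartile, the bound first written, this did not decide. The median was then tried as the bound, dropped because the result was known, and later taken up again. This changed the conclusion but none of the values, so the conclusion is worth less than one from a rule set beforehand. By that bound the tables argue against a change in share as the whole cause, while a part in it stays open. The time of day at which livers were taken also stays open. Clock genes went both ways, Per1 and Nr1d1 lower (log2 changes -1.04 and -0.58) and Usp2 and Wee1 higher (1.24 and 0.80). Of these only Per1 was called. A test for a shared direction can miss such changes, so neither its pass nor its failure decides the question. The clock list gave a camera adjusted p of 0.172, but was called higher without control library 3 (0.0304) and without gelADSC library 3 (0.000625), and the median absolute difference of its genes was 0.64 between groups and 0.77 between the gelADSC libraries, a comparison whose wording was changed after its result was known.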
